A study of Mus musculus with 12 samples.

How the data were processed

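The series holds 12 libraries of organoids from MMTV-Neu mouse mammary tumours, 4 per group. Per the labels, lentivirus at a multiplicity of infection of 20 carried a non-targeting short hairpin RNA or 1 of 2 hairpins against Cldn7, infected organoids were selected with puromycin at 3 µg/ml for 3 days, and the medium held 2.5 nM FGF2. Per the labels, organoids were then kept in collagen I for 5 days, and libraries were made from oligo-dT selected RNA with a kit of the NEBNext Ultra series. A short hairpin RNA is processed by the cell into a small RNA that lowers the messenger RNA it matches. The labels do not say that the 4 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

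The deposited values are raw read counts per gene, 1 column per library, identified by NCBI Gene number and symbol; they were not normalized. The submitters' processing notes name FastQC 0.74, Trimmomatic 0.39, DESeq2 1.34.0 and the genome build mm10, without saying what each was used for. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here, and reads of overlapping or near-identical genes may have been assigned in ways that cannot be seen from the counts. Of 25861 gene numbers, 25233 were found in the RefSeq gene table of GRCm38.p6 and 23596 of these had the same symbol. Coordinates come from GENCODE M21 on GRCm38, the assembly also called mm10. Total counts per library were 34988358 to 76329473, at which the filter for low counts kept at least 99.97% of the counts of each library. Within groups no 2 libraries came near the agreement that a duplicate would show: the chi-square of their counts per degree of freedom was 54.2 to 612.

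The following choices were made before the data were examined: the groups, the tests, the gene lists, the rule for the genes to be named and the other settings to be tried. Genes were filtered with edgeR's filterByExpr by group, which kept 17025 and left out 8836, and libraries were scaled by the trimmed mean of M-values. Differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) over all 12 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The contrasts were both hairpins against the control, each hairpin against the control, and hairpin 2 against hairpin 1. The primary model had the group alone, and the model with the replicate number as a block was the second, also set beforehand.

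The replicate numbers were then found to pair the libraries. The deviations from the group means correlated between 0.855 and 0.916 for libraries with the same number in different groups and between -0.807 and 0.727 for other numbers, and 12 of 12 libraries were closest to their own number. The pairing comes from the numbers in the titles and these correlations, since the labels give no shared animal or day. Both models are therefore reported, and the gene values with the replicate number in the model lead the text. The single values of Cldn7, Acta2 and Nfe2l2 were also tested with exact two-sided permutation tests on log2 CPM with a prior count of 2. These tests exchanged libraries freely and did not keep the pairing by replicate number.

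The 32 lists hold 716 genes, of which 688 were tested: smooth muscle contractile, actin regulator, claudin, tight junction, adherens junction, desmosome, luminal, basal, mesenchymal, collagen, protease, TGF-beta, YAP-TAZ, ERBB, cell cycle, interferon, p53, hypoxia and glycolysis, endoplasmic reticulum stress, cholesterol, cytokine, immediate early, mitochondrially encoded and histone genes, and markers of fibroblasts, pericytes, endothelium, macrophages, lymphocytes, adipocytes, Schwann cells and skeletal muscle. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. In the model without the replicate number, the estimated correlation kept the smooth muscle list over both hairpins and for hairpin 2 (adjusted p = 0.00893 and 0.0114) and no other list call; with the replicate number it kept none. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called with the replicate number the smooth muscle list over both hairpins (adjusted p = 0.0433) and for hairpin 2 (0.0299), and the pericyte list for hairpin 2 (0.0405).

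Genes were named by a rule. It took Cldn7 and Acta2 in every contrast; the 12 largest changes in each direction for both hairpins together, among genes past the threshold with a mean of at least 2 CPM, the same sign for each hairpin and a symbol that is not an unnamed locus; the 5 largest in each direction for the other contrasts; and up to 4 members of smallest p in each list. Nfe2l2, Gsta3, Gclm and some further list members were chosen after their values were seen. The values of 1 list member are not reported here. To find genes that may share reads with copies, 50-base stretches of each gene's transcripts were sampled every 10 bases and looked up in the transcripts of genes elsewhere; 16175 genes, or 95%, had a value.

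The other settings, set beforehand, were DESeq2, median-of-ratios and upper-quartile scaling, no filter, a stricter filter of 1 CPM in 4 libraries, a robust dispersion trend, limma-voom, a test against a 1.5-fold change, fits of only the 2 groups compared, and leaving out each of the 12 libraries. The same settings with the replicate number in the model, fits of replicates 1 and 2 or of 3 and 4 alone, and a fit of all hairpin libraries as 1 group, as well as the list tests with the replicate number under other settings, were added after seeing the data. The tests were run on simulated data with 200 of 17025 genes changed. These data were drawn with the replicate-number effects and dispersions fitted by the model with the replicate number. They therefore favour that model and cannot test the choice between the 2 models. For both hairpins against the control, the model with the replicate number recovered 70% of 1.5-fold and 96% of 2-fold changes with 10 false calls, and the model without it recovered 15% and 55% with 0 false calls. The analysis used edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.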

Results

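Gene expression was measured by RNA sequencing in organoids from mammary tumours of MMTV-Neu mice, in which a mammary tumour virus promoter drives the Neu (Erbb2) oncogene in the mammary epithelium. The organoids carried 1 of 2 short hairpin RNAs against Cldn7, here called hairpin 1 and hairpin 2, or a non-targeting hairpin, here called the control. Cldn7 encodes claudin 7, a membrane protein of epithelial tight junctions. The organoids were kept in 3D collagen I for 5 days, a setting in which tumour epithelium can invade, and the stated question was the role of Cldn7 in invasion and metastasis. Each group held 4 libraries, numbered 1 to 4, so that 12 libraries were compared. Total counts ranged from 34988358 to 76329473 per library. They lay between 34988358 and 44645514 in replicates 1 and 2, and between 68581024 and 76329473 in replicates 3 and 4 of every group. Of 25861 genes in the table, 17025 had enough counts to be tested.

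Cldn7 (NCBI Gene 53624; mouse chromosome 11, 69964779 to 69967885, GRCm38, plus strand, a protein-coding gene) was examined first, since its level checks the labels. It stood at 142 ± 34.6 CPM (counts scaled to library size; SD, n = 4) in the control, 33.6 ± 7.15 (SD, n = 4) with hairpin 1 and 28.4 ± 4.29 (SD, n = 4) with hairpin 2. Cldn7 fell by 2.20 on the log2 scale (SE 0.16) over both hairpins, which left 21.8% of the control level (edgeR adjusted p = 0.000699). It fell by 2.08 (SE 0.20) with hairpin 1, leaving 23.7% (edgeR adjusted p = 0.0116), and by 2.32 (SE 0.20) with hairpin 2, leaving 20.0% (edgeR adjusted p = 0.00423). All 8 hairpin libraries lay below all 4 controls, and the exact two-sided permutation p was 0.00202 for 8 against 4 libraries and 0.0286 for each hairpin alone. These are the smallest values that free exchange of the libraries, without regard to the replicate number, can give. The level with hairpin 2 minus hairpin 1 was -0.24 (SE 0.20) on the log2 scale, which was not past the threshold (edgeR adjusted p = 1; 0.149 with the replicate number in the model). With only the libraries of the 2 groups compared in the fit, the fold changes were -2.06 and -2.32 but the edgeR adjusted p rose to 0.259 for hairpin 1 and 0.0578 for hairpin 2. The hairpin 1 call was also lost when control replicate 1 or 2 or hairpin 1 replicate 1, 2 or 4 was left out (edgeR adjusted p = 0.0818, 0.0583, 0.145, 0.138 and 0.0902).

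**Figure D1:**
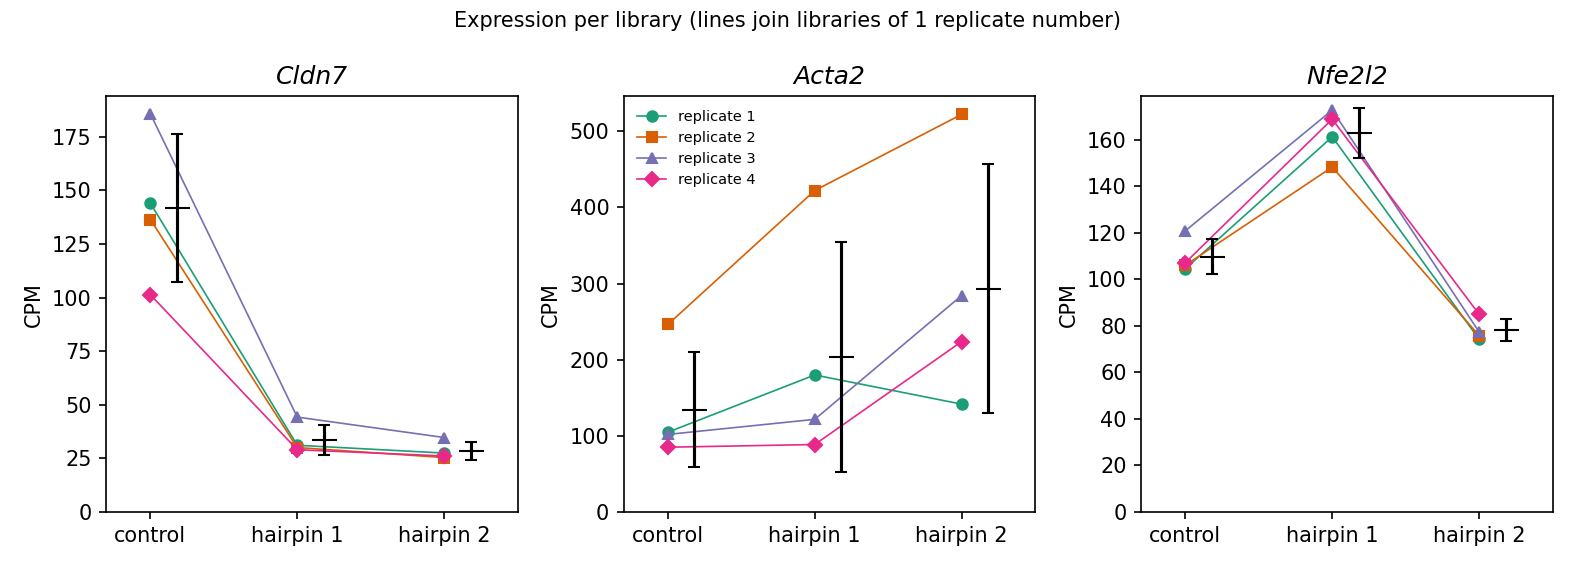
Expression of Cldn7, Acta2 and Nfe2l2 in CPM (vertical axis) in each of the 12 libraries, by group (horizontal axis); each line joins the libraries of 1 replicate number, and the black mark and bar give the group mean and SD (n = 4). Cldn7 averaged 142, 33.6 and 28.4 CPM in the control, hairpin 1 and hairpin 2 groups, and Nfe2l2 averaged 110, 163 and 78.1 CPM.

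The replicate number set most of the variation between libraries. The first principal component of log2 CPM held 70.8% of the variance and separated replicates 1 and 2 from replicates 3 and 4 in every group. Immune transcripts followed the same division: the macrophage markers had a median log2 CPM of 1.56 in replicates 1 and 2 and -2.70 in replicates 3 and 4. Ptprc, the pan-leukocyte gene, stood at 2.18 to 9.21 CPM in the libraries of replicates 1 and 2 and at 0 to 0.179 CPM in those of replicates 3 and 4. Each group held both kinds of library in equal number. The biological coefficient of variation was 0.648 when the replicate number was left out of the model and 0.141 when it was included. Fold changes, SEs and adjusted p below come from edgeR's quasi-likelihood test with the replicate number in the model, unless the text says otherwise. Without it, the design set as the primary one, Cldn7 was the only gene past the threshold against the control, and Nfe2l2 the only one between the hairpins.

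**Figure D2:**
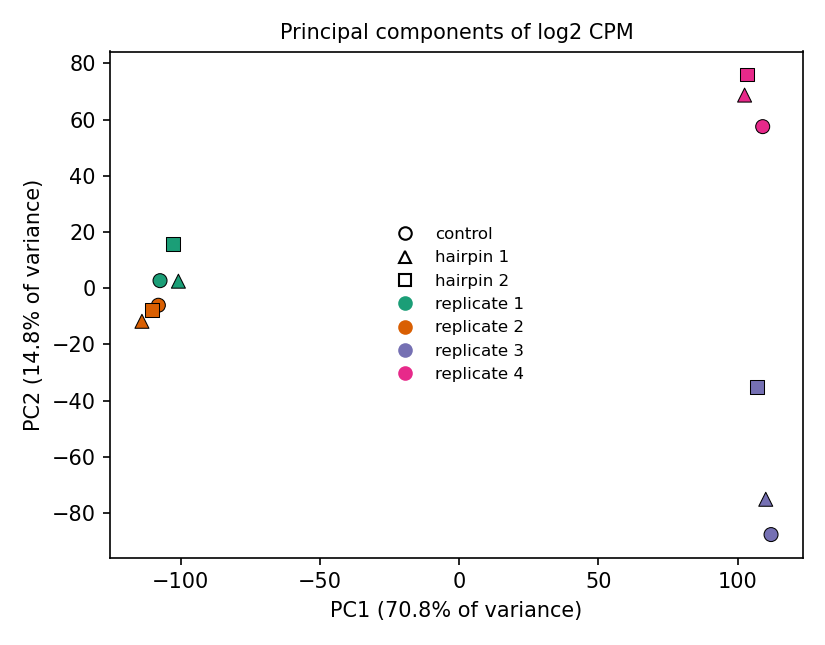
Principal components 1 and 2 of log2 CPM (axes in log2 units, with the share of variance each holds) for the 12 libraries; colour gives the replicate number and shape the group. Component 1, with 70.8% of the variance, separates replicates 1 and 2 from replicates 3 and 4 in all 3 groups.

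The first comparison asked which genes changed with less Cldn7, taking both hairpins together against the control. Of 23 measured genes of the smooth muscle contractile apparatus, 5 rose and 18 did not pass, and the list as a group passed camera's test (adjusted p = 2.25e-08, and adjusted p = 0.517 with an estimated correlation). Cnn1, which encodes the actin-binding calponin 1, rose by 1.83 (SE 0.30, log2), Myh11, the smooth muscle myosin heavy chain, by 1.58 (SE 0.29), Actg2, the enteric smooth muscle actin, by 1.33 (SE 0.26), and Tagln, which encodes transgelin, by 1.14 (SE 0.21). In the control, Cnn1, Myh11, Actg2 and Tagln averaged 3.41, 7.8, 1.47 and 57.8 CPM, so Cnn1 and Actg2 rose from low levels. Casein Csn1s1, a milk protein, rose from 91.1 CPM in the control to 265 and 187 CPM with the hairpins, and the stem cell receptor Lgr5 rose by 1.30 (SE 0.23). Among the genes that fell most after Cldn7 were Cnmd, which encodes chondromodulin (-1.37, SE 0.24), the homeobox gene Msx3 (-1.30, SE 0.25), and Cxcr4, the receptor of the chemokine Cxcl12 (-0.87, SE 0.15). With hairpin 1 alone, Cnn1, Myh11, Actg2, Tagln, Lgr5, Cnmd, Msx3 and Cxcr4 had the same sign but did not pass. Their edgeR adjusted p ran from 0.103 for Actg2 to 0.291 for Msx3. Each of them passed with hairpin 2 alone, and Csn1s1 passed with each hairpin. In all, 143 genes rose and 161 fell with the replicate number in the model, 304 in total, of which 22 rose and 5 fell by more than 2-fold. Without the replicate number 1 gene passed, Cldn7, and 406 genes had an unadjusted p under 0.05 in edgeR; DESeq2 without it called 43. With the replicate number and 1 library left out at a time, the count ranged from 39 to 554, and 48 passed when both hairpins formed 1 group. DESeq2 with the replicate number called 1161.

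The smooth muscle genes past the threshold were Actg2, Cnn1, Csrp1, Myh11 and Tagln, with 5 higher and 0 lower, against 14 higher and 1 lower adjusted over the list alone, and 22 had a positive fold change. Csrp1, a LIM-domain protein of the actin cytoskeleton, rose by 0.40 (SE 0.04; edgeR adjusted p = 0.00445). Acta2 (NCBI Gene 11475; chromosome 19, 34241090 to 34255590, GRCm38), which encodes alpha smooth muscle actin, stood at 134 ± 75.1, 203 ± 151 and 293 ± 164 CPM (SD, n = 4 each) in the control, hairpin 1 and hairpin 2 groups. Its log2 fold change over both hairpins was 0.82 (SE 0.20) and higher than the control in 8 of 8 pairs of libraries with the same number, but it did not pass (edgeR adjusted p = 0.0653; 1 without the replicate number). The list as a group was higher than other genes (camera adjusted p = 2.61e-11 without the replicate number and 2.25e-08 with it). The adjusted p = 0.00893 with an estimated correlation without the replicate number and 0.517 with it. The list follows the theme of the title of this same series, so it is not independent evidence of a direction.

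The lists of YAP-TAZ targets, basal genes and mesenchymal genes were also higher. The YAP-TAZ targets passed (camera adjusted p = 2.34e-05, and adjusted p = 0.612 with an estimated correlation), where 1 of 20 rose, the receptor tyrosine kinase Axl (0.60, SE 0.11), and 8 were higher adjusted over the list alone. Basal and myoepithelial genes were higher (camera adjusted p = 0.000255, and adjusted p = 0.612 with an estimated correlation). Of 25 of them, 3 rose and 1 fell: the basement membrane collagen Col4a2 (0.68, SE 0.08), the Notch ligand Jag2 (0.61, SE 0.12) and Lgr5 rose, and the tetraspanin Tspan8 fell by 0.31 (SE 0.06). Adjusted over the list alone, 9 were higher and 1 lower. Mesenchymal genes were higher (camera adjusted p = 1.56e-06, and adjusted p = 0.612 with an estimated correlation), where 1 of 25 rose, the matrix proteoglycan Bgn (0.72, SE 0.13), and 9 adjusted over the list alone. Snai2, a transcription factor of epithelial-mesenchymal transition, was at 0.69 (SE 0.16; edgeR adjusted p = 0.0609), and the mesenchymal cadherin Cdh11 at 0.62 (SE 0.14; edgeR adjusted p = 0.0605).

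Fibroblast and pericyte markers moved with these groups. Pericyte and vascular smooth muscle markers were higher (camera adjusted p = 0.000255, and adjusted p = 0.517 with an estimated correlation), with Pdgfrb, a growth factor receptor of mesenchymal cells, up by 0.47 (SE 0.10) as 1 of 14, and 4 adjusted over the list alone. Fibroblast markers were higher (camera adjusted p = 0.000812, and adjusted p = 0.612 with an estimated correlation), with the fibril-associated collagen Col14a1 up by 1.07 (SE 0.20) as 1 of 20, and 7 adjusted over the list alone. The fibroblast list was not past the threshold without the replicate number (camera adjusted p = 0.116). Endothelial markers (0 of 17 passed, camera adjusted p = 0.202), macrophage markers (0 of 24; 0.808), lymphocyte markers (0 of 18; 0.270), adipocyte markers (0 of 10; 0.229), Schwann cell and neural markers (0 of 12; 0.202) and skeletal muscle markers (0 of 16; 0.808) were not past the threshold. Adjusted over the list alone, 1 Schwann cell or neural marker was lower and none of the others in these 6 lists.

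Among junction and epithelial identity genes other than Cldn7, those past the threshold were Cldnd1, Cdh3, Ehf, Nectin1 and Epcam. Of 12 claudin and claudin-domain genes, 1 fell, Cldnd1 (-0.23, SE 0.05), over all genes and adjusted over the list alone, and Cldn4 was at 0.49 (SE 0.17; edgeR adjusted p = 0.157). Of 25 adherens junction and epithelial identity genes, 3 rose and 1 fell. P-cadherin Cdh3, found in basal mammary cells, rose by 0.86 (SE 0.14), the epithelial transcription factor Ehf by 0.28 (SE 0.05) and the adhesion gene Nectin1 by 0.33 (SE 0.06), while the epithelial adhesion molecule Epcam fell by 0.25 (SE 0.05). Of these genes 3 were higher and 5 lower adjusted over the list alone. None of 25 tight junction and polarity genes or 19 desmosome genes passed, over all genes or over the list alone. As groups, the claudins (camera adjusted p = 0.808), tight junction genes (0.808), adherens junction genes (0.270) and desmosome genes (0.808) were not past the threshold. The claudins' median (0.00032) and mean relative to all genes (0.010) were close to 0 while camera's direction was down, and their medians over the 4 pairs of libraries averaged -0.061 ± 0.05 (SD, n = 4) with hairpin 1 and -0.046 ± 0.13 with hairpin 2. The tight junction mean was below that of all genes while camera's direction was up. Luminal genes as a group did not pass either (camera adjusted p = 0.321). Of 24, Csn1s1 and Wfdc18, a secreted whey-acidic-protein family member (0.41, SE 0.08), rose and the retinaldehyde dehydrogenase Aldh1a3 fell by 0.34 (SE 0.07). Adjusted over the list alone, 4 were higher and 1 lower.

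Several further groups passed camera's test. Cell cycle genes were higher, 26 of 28 with a positive sign and 0 past the threshold singly (camera adjusted p = 0.00182, and adjusted p = 0.836 with an estimated correlation). Hypoxia and glycolysis genes were lower (camera adjusted p = 0.000768, and adjusted p = 0.612 with an estimated correlation), where the phosphofructokinase Pfkp fell by 0.39 (SE 0.07) as 1 of 24 and 3 were lower adjusted over the list alone. Collagens and matrix genes (camera adjusted p = 0.000812, and adjusted p = 0.612 with an estimated correlation) were higher, although Ltbp2, a latent TGF-beta binding protein, fell by 0.48 (SE 0.09). Col4a2 was the 1 of 25 that rose, and 3 were higher and 1 lower adjusted over the list alone. Interferon response genes (camera adjusted p = 0.00670, and adjusted p = 0.836 with an estimated correlation), matrix proteases (0.0132, and adjusted p = 0.836 with an estimated correlation) and immediate early genes (0.0449, and adjusted p = 0.654 with an estimated correlation) were higher with 0 members past the threshold. Among them 3 immediate early genes were higher adjusted over the list alone. Without the replicate number, hypoxia genes (camera adjusted p = 0.156), collagens (0.0755), interferon genes (0.0593), proteases (0.124) and immediate early genes (0.0525) did not pass. Actin regulators (0 of 30 passed, camera adjusted p = 0.202), TGF-beta response genes (1 lower of 24; 0.808), ERBB receptors and ligands (0 of 22; 0.741), p53 response genes (1 lower of 24; 0.478) and endoplasmic reticulum stress genes (0 of 22; 0.0796) did not pass as groups. Neither did cholesterol synthesis genes (0 of 23, camera adjusted p = 0.229), cytokine genes (0 of 32; 0.658), mitochondrially encoded genes (0 of 13; 0.0914) or histone genes (0 of 13; 0.808). With an estimated correlation and the replicate number in the model, 0 of the 32 lists passed. Of the 12 lists called, the smooth muscle, basal, mesenchymal, YAP-TAZ, fibroblast and pericyte lists passed camera's test whichever library was left out. The collagen (camera adjusted p = 0.0935) and hypoxia (0.0956) calls were lost without control replicate 3, and the cell cycle call without control replicate 4 (0.406). The interferon call was lost without control replicate 2, hairpin 1 replicate 2 or hairpin 2 replicate 4 (camera adjusted p = 0.50, 0.0786 and 0.116), and the protease call without control replicate 3 or 4, hairpin 1 replicate 4 or hairpin 2 replicate 3 (0.324, 0.406, 0.0903 and 0.0619). The protease mean turned to -0.15 in replicates 1 and 2 alone. The immediate early call was lost without control replicate 1 or 3, hairpin 1 replicate 1 or 4, or hairpin 2 replicate 1 or 3 (camera adjusted p = 0.341, 0.192, 0.104, 0.0647, 0.0844 and 0.179).

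With hairpin 1 alone, Csn1s1 rose by 1.56 (SE 0.18), the homeobox gene Irx4 by 1.28 (SE 0.23), the zinc finger gene Tshz2 by 1.07 (SE 0.20), the podocalyxin-like gene Podxl2 by 0.94 (SE 0.14) and the chloride channel accessory gene Clca4b by 1.66 (SE 0.29). Mogat1, an acyltransferase of triglyceride synthesis, fell by 1.09 (SE 0.12), Scrg1 by 0.82 (SE 0.11), the amino acid transporter Slc6a15 by 0.81 (SE 0.12) and the osteocalcin-related Bglap3 by 0.96 (SE 0.10). Clca4b and Bglap3 are uncertain, since 25.1% and 13.9% of their sampled sequence also occurs in transcripts of other genes. In all 65 genes rose and 59 fell, 124 in total; 1 passed without the replicate number, where 307 had an unadjusted p under 0.05 and DESeq2 called 27. With the replicate number, 390 passed when the fit held only the hairpin 1 and control libraries, and DESeq2 called 607.

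Of the smooth muscle list, Csrp1 rose by 0.39 (SE 0.05) with hairpin 1 as 1 of 23, with 5 higher adjusted over the list alone, and Acta2 was at 0.50 (SE 0.22; edgeR adjusted p = 0.384). The list's median over the 4 pairs of libraries was 0.27 ± 0.14 (SD, n = 4). Camera gave an adjusted p of 4.75e-06 for this list (adjusted p = 0.767 with an estimated correlation). Cell cycle genes were higher, all 28 with a positive sign and 0 past the threshold (camera adjusted p = 2.19e-06, and adjusted p = 0.968 with an estimated correlation). YAP-TAZ targets were higher (camera adjusted p = 0.00495, and adjusted p = 0.968 with an estimated correlation), where F3, which encodes tissue factor, rose by 0.48 (SE 0.07). In the basal list (camera adjusted p = 0.0290, and adjusted p = 0.968 with an estimated correlation) Col4a2 rose by 0.61 (SE 0.09) and Tspan8 fell by 0.48 (SE 0.07). Mesenchymal genes, actin regulators and pericyte markers also passed as groups with 0 members past the threshold, each with a camera adjusted p of 0.0290 (adjusted p = 0.968, 0.767 and 0.968 with an estimated correlation). The basal (camera adjusted p = 0.0628), mesenchymal (0.326) and pericyte lists (0.130) did not pass without the replicate number. With it, the smooth muscle and cell cycle lists passed whichever library was left out. The other 5 calls were lost without control replicate 3 (camera adjusted p = 0.186 for actin regulators and YAP-TAZ targets, 0.369 for basal genes, 0.323 for mesenchymal genes and pericyte markers). The basal and mesenchymal calls were also lost without control replicate 4 (camera adjusted p = 0.211 each) or hairpin 1 replicate 4 (0.165 each), the basal call without hairpin 1 replicate 1 (0.0926), the mesenchymal call without hairpin 1 replicate 2 (0.0512), and that of actin regulators without hairpin 1 replicate 3 or 4 (0.0585 each). Cldnd1 fell by 0.32 (SE 0.05). The count of 124 ranged from 2 to 344 with 1 library left out.

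With hairpin 2, 8 contractile and 8 mesenchymal genes rose. Cnn1 rose by 2.49 (SE 0.33), Myh11 by 2.03 (SE 0.32), Tagln by 1.46 (SE 0.23), and Actg2 by 1.46 (SE 0.29). The tropomyosin Tpm2 rose by 0.94 (SE 0.19), Tgfb1i1, which encodes the focal adhesion protein Hic-5, by 1.04 (SE 0.18) and Acta2 by 1.14 (SE 0.23; edgeR adjusted p = 0.0193). With Csrp1 (0.41, SE 0.05), 8 of 23 rose, and 14 were higher and 1 lower adjusted over the list alone. The list's median over the 4 pairs was 0.56 ± 0.14 (SD, n = 4, camera adjusted p = 1.42e-07, and adjusted p = 0.513 with an estimated correlation). In all 482 genes rose and 499 fell, 981 in total; 1 passed without the replicate number, where 606 had an unadjusted p under 0.05 and DESeq2 called 61. With the replicate number DESeq2 called 1860, and edgeR called 342 to 1076 with 1 library left out at a time. The largest changes outside that list were in Dlk1, a Notch-family ligand of progenitor cells (2.64, SE 0.59), the galactosyltransferase B3galt2 (1.99, SE 0.30), and the opioid precursor Penk (1.75, SE 0.41), which rose. Those that fell were Cnmd (-1.88, SE 0.29), Msx3 (-1.79, SE 0.32), the carbonic anhydrase-related Car8 (-1.78, SE 0.31) and the retinol dehydrogenase Rdh12 (-1.61, SE 0.16). In the controls, Penk was far higher in replicate 4 and Msx3 and Car8 in replicate 3 than in the other 3 libraries. Dlk1, B3galt2 and Penk were low in the control group, at 2.65, 1.44 and 1.89 CPM on average.

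Mesenchymal genes rose with hairpin 2, 8 of 25 (15 adjusted over the list alone), among them Snai2 (0.99, SE 0.18), the homeobox transcription factor Prrx1 (1.04, SE 0.16), Bgn (0.97, SE 0.15) and the matrix protein Postn (1.05, SE 0.21). Their camera adjusted p was 1.42e-07 and adjusted p = 0.600 with an estimated correlation. Basal genes rose in 7 of 25 (14 adjusted over the list alone), with Lgr5 at 1.62 (SE 0.25) and Col4a2 at 0.74 (SE 0.09). Their camera adjusted p was 8.42e-05 and adjusted p = 0.600 with an estimated correlation. Collagens (5 higher and 1 lower of 25, camera adjusted p = 1.36e-05), YAP-TAZ targets (4 higher of 20; 7.33e-05), with Axl at 0.77 (SE 0.12), and interferon response genes (2 higher of 27; 1.14e-05), with the membrane protein Bst2 at 0.57 (SE 0.14), were also higher. The adjusted p was 0.600, 0.600 and 0.667 with an estimated correlation. Over the list alone the higher members numbered 13, 6 and 8. Stromal markers moved with them. Pericyte markers rose in 4 of 14 (9 adjusted over the list alone), with Pdgfrb at 0.67 (SE 0.11). Fibroblast markers were higher in 4 and lower in 1 of 20 (7 and 1 adjusted over the list alone), with the proteoglycan Dcn at 1.02 (SE 0.17). Their camera adjusted p were 0.000149 and 0.000291, and adjusted p = 0.513 and 0.600 with an estimated correlation. Prrx1, Bgn, Pdgfrb and Col4a2 each stood far higher in the hairpin 2 library of replicate 4 than in the other 3 of that group. The fibroblast list did not pass without the replicate number (camera adjusted p = 0.119).

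Hypoxia and glycolysis genes were lower with hairpin 2 (camera adjusted p = 0.000105, and adjusted p = 0.600 with an estimated correlation), where 4 were lower and 1 higher of 24, and 11 lower and 1 higher adjusted over the list alone. Pfkp fell by 0.68 (SE 0.08) and the aldolase Aldoa by 0.51 (SE 0.12). Endoplasmic reticulum stress genes (2 lower of 22, 3 over the list alone, camera adjusted p = 0.0280, and adjusted p = 0.824 with an estimated correlation), cholesterol synthesis genes (0 of 23; 0.0218, and adjusted p = 0.869 with an estimated correlation) and the mitochondrially encoded genes (0 of 13; 0.000357, and adjusted p = 0.605 with an estimated correlation) were lower as groups. Most mitochondrially encoded genes differed in count between replicates 1 and 2 and replicates 3 and 4, so this list is uncertain. Immediate early genes (1 higher of 24, 4 over the list alone, camera adjusted p = 0.00931, and adjusted p = 0.600 with an estimated correlation) and matrix proteases (1 higher and 1 lower of 28, 4 and 1 over the list alone; 0.0209, and adjusted p = 0.824 with an estimated correlation) were higher. The endoplasmic reticulum stress (camera adjusted p = 0.0552), cholesterol (0.0827), mitochondrially encoded (0.113) and protease lists (0.143) did not pass without the replicate number. With it, the stress call was lost without control replicate 1 or 3 or hairpin 2 replicate 3 (camera adjusted p = 0.0674, 0.308 and 0.503), the protease call without control replicate 3 or 4 or hairpin 2 replicate 3 (0.189, 0.321 and 0.196), the cholesterol call without control replicate 3 or hairpin 2 replicate 3 (0.576 and 0.503), and the immediate early call without control replicate 1 or hairpin 2 replicate 3 (0.0651 and 0.0528). In replicates 1 and 2 alone the protease mean turned to -0.13 and the cholesterol mean to 0.044. Aldoa was far higher in control replicate 3 than in the other controls. Among epithelial genes Cdh3 rose by 1.11 (SE 0.16), Ehf by 0.53 (SE 0.06) and Wfdc18 by 0.81 (SE 0.10), while Epcam fell by 0.34 (SE 0.06) and Aldh1a3 by 0.57 (SE 0.08). The order of the counts, 124 for hairpin 1 and 981 for hairpin 2, turned round to 390 and 97 when each fit held only the libraries of the 2 groups compared.

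The genes changed by both hairpins were compared next. Besides Cldn7, the genes that rose with each hairpin included Csn1s1, Irx4, Tshz2, Col4a2 and Csrp1, and those that fell with each included Scrg1, Bglap3, Mogat1 and Slc6a15. In all 52 genes changed the same way with each hairpin, 33 higher and 19 lower, where independent lists of these sizes would share 1.84 and 1.73. The count of 52 depended strongly on single libraries, with its range given under the dependence on the processing. In 20 simulations of unchanged groups against the same controls the mean overlap was 0.15 and the highest 2. No gene was changed in them, so few calls and a small overlap were set in advance. They do not test whether the hairpins agree, since separate effects of each hairpin were not simulated. Since the hairpins share their controls, their fold changes correlate across genes without any effect: the correlation was 0.472 where simulation gave 0.503, and the covariance was 0.0632 against 0.0450, a difference of 0.0181. The controls were also split so that each hairpin had its own, which left each hairpin 2 replicate numbers, not those of the other. These fits of 2 against 2 libraries are smaller than those behind the 52 genes and the 0.472, so the values are not like for like. The correlation over 6 splits lay between -0.0111 and 0.0682 and the overlap between 1 and 27 genes. In the same splits 0 to 17 genes went opposite ways: 17 beside the 27 shared, 5 beside 11, 2 beside 10 and 0 in the other 3 splits. Without the replicate number 1 gene, Cldn7, was shared, and the covariance was 0.068 where simulation gave 0.398, a difference of -0.330. The correlation over the split controls then lay between -0.468 and 0.00303. These values do not tell whether the hairpins agree. That simulation drew replicate differences as independent noise, while in the data they are balanced across groups. Those splits set all libraries of a hairpin against part of the controls, so replicate differences entered the 2 fold changes with opposite signs. Another 5 genes went opposite ways: Nfe2l2, Gsta3, Gclm and Pepd, which rose with hairpin 1 and fell with hairpin 2, and Tmprss4, which did the reverse; they were named after their values were seen.

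The last comparison set hairpin 2 against hairpin 1, which target the same gene. Nfe2l2 (NCBI Gene 18024; chromosome 2, 75675513 to 75704641, GRCm38), which encodes NRF2, the transcription factor of the oxidative stress response, was higher than the control with hairpin 1 and lower with hairpin 2. It stood at 110 ± 7.54, 163 ± 10.8 and 78.1 ± 4.77 CPM (SD, n = 4 each) in the control, hairpin 1 and hairpin 2 groups, which did not overlap. The exact two-sided permutation p was 0.0286 for each pair of groups, the smallest possible when libraries are exchanged freely. Splits that keep the pairing by replicate number can reach no share under 0.125. Nfe2l2 was also chosen after its values were seen, so this p is not independent support. Its log2 fold change was 0.57 (SE 0.06) with hairpin 1 and -0.49 (SE 0.06) with hairpin 2, and it fell by 1.06 (SE 0.06) from hairpin 1 to hairpin 2 (edgeR adjusted p = 5.24e-05, and 0.00111 without the replicate number). Gsta3, a glutathione transferase, was lower with hairpin 2 than hairpin 1 by -1.76 (SE 0.12), and Gclm, a subunit of the enzyme that makes the glutathione precursor, by -0.80 (SE 0.07). The matrix gene Mfap4 was higher with hairpin 2 by 2.07 (SE 0.37), the retinoic acid binding protein Crabp1 by 1.90 (SE 0.29), the imprinted non-coding RNAs Meg3 and Rian by 1.60 (SE 0.28) and 1.60 (SE 0.29), and Gsg1l by 1.52 (SE 0.20). Car8 (-1.69, SE 0.30), Ccnjl (-1.38, SE 0.23), Rdh12 (-1.25, SE 0.16) and Ceacam10 (-1.28, SE 0.26) were lower. In all 267 genes were higher and 318 lower with hairpin 2, 585 in total; Nfe2l2 alone passed without the replicate number, where 490 genes had an unadjusted p under 0.05 and DESeq2 called 49. With the replicate number DESeq2 called 1436, and edgeR called 165 to 672 with 1 library left out at a time. Mfap4 in every group, and Meg3 in the control and hairpin 1 groups, were far higher in replicate 4 than in the other 3 libraries.

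Between the hairpins, interferon response genes were higher with hairpin 2, all 27 with a positive sign, with 1 past the threshold and 8 adjusted over the list alone (camera adjusted p = 1.45e-06, and adjusted p = 0.796 with an estimated correlation). Mesenchymal genes (2 higher of 25, 11 over the list alone, camera adjusted p = 0.000342), with Prrx1 at 0.85 (SE 0.16), and collagens (2 higher and 1 lower of 25, 9 and 1 over the list alone; 0.000462) were higher. So were basal genes (2 higher of 25, 2 over the list alone; 0.00873), with Tspan8 at 0.35 (SE 0.07). Skeletal muscle (0 of 16; 0.00873), smooth muscle (0 of 23, 2 higher and 1 lower over the list alone; 0.0256) and pericyte genes (0 of 14, 2 over the list alone; 0.0386) were higher too, although no member passed. Acta2 was at 0.64 (SE 0.23; edgeR adjusted p = 0.151), higher in 3 of 4 pairs. Cell cycle genes (0 of 28, camera adjusted p = 0.000462), cholesterol genes (0 of 23; 0.00873), hypoxia genes (4 lower and 1 higher of 24, 6 and 1 over the list alone; 0.0225), with Pfkp at -0.58 (SE 0.08), and mitochondrially encoded genes (0 of 13; 4.44e-05) were lower. Each of these lists had an adjusted p = 0.796 with an estimated correlation. The collagen (camera adjusted p = 0.136), hypoxia (0.105) and pericyte lists (0.177) did not pass without the replicate number, and immediate early genes did (0.0412, against 0.0636 with it). With it, the interferon, mesenchymal and mitochondrially encoded lists passed whichever library was left out. The other 8 calls were lost without hairpin 2 replicate 3 (camera adjusted p = 0.251 for smooth muscle, basal and pericyte genes, 0.305 for cell cycle and hypoxia genes, 0.937 for cholesterol genes and 0.060 for collagens and skeletal muscle genes). Without hairpin 1 replicate 3 the smooth muscle, basal, pericyte and skeletal muscle calls (camera adjusted p = 0.0698 each) and the cholesterol call (0.111) were lost, and without hairpin 1 replicate 4 the smooth muscle (0.171), pericyte (0.125) and skeletal muscle calls (0.0597). Leaving out hairpin 2 replicate 1 ended the skeletal muscle call (camera adjusted p = 0.0643), replicate 2 the smooth muscle call (0.0518) and replicate 4 the pericyte call (0.0749). The cholesterol mean turned to 0.0037 in replicates 1 and 2 alone. Outside them, Wfdc18 (0.80, SE 0.10), Ehf (0.49, SE 0.06) and the fibroblast proteoglycan Dcn (0.91, SE 0.17) were higher with hairpin 2, and Aldh1a3 (-0.44, SE 0.08), F3 (-0.54, SE 0.07) and the ERBB-pathway transcription factor Etv5 (-0.48, SE 0.10) were lower. Etv5 is uncertain, since 26.7% of its sampled sequence also occurs in transcripts of other genes.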

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

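Of the tests in this part, those on other cell types, on scaling, on the amount of Cldn7 left and on other splits of the samples were chosen after the result was seen. The tests on depth, immune transcripts, near-identical genes and NRF2 targets were set before their own result was seen.

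Replicates 1 and 2 stood apart from replicates 3 and 4 in every group, with 4482 genes called between the sets by edgeR, 1535 of them higher in replicates 3 and 4. That test took all libraries as independent, although libraries with the same number were alike across groups. Each set therefore held only 2 separate replicate numbers. The calls, and the shares of calls given below, overstate the evidence and only describe these libraries. Depth, which was lower in replicates 1 and 2, is argued against as the whole cause, since 94.8% of these calls remained after all libraries were thinned to the lowest total. Different counting of genes with near-identical copies may account for part of it: of 474 genes with 50% or more of their sampled sequence found elsewhere, 82.7% were lower in replicates 3 and 4 and 0 higher, against 12.4% lower and 10.4% higher of 11311 genes with none. Mitochondrial ATP6 (98.4% shared) fell from 4520 to 2.46 CPM while CYTB (0% shared) stood at 3570 and 3800, though ATP8 (0% shared) went from 2680 to 0.511. The lookup covered annotated transcripts only, so 0% shared does not show that a gene has no copy elsewhere in the genome. Mitochondrial genes gave rise to this idea and are among the genes tested. Leukocyte transcripts were part of the division: 21 of 24 macrophage and 13 of 18 lymphocyte markers were higher in replicates 1 and 2, and 0 in replicates 3 and 4. How much of the division immune cells account for stays open. Of all calls 34.2% were higher in replicates 3 and 4, between the bounds set for and against immune cells as the cause. The design names no biological difference between the replicate numbers that could be tested.

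Smooth muscle genes were higher in the hairpin libraries, with a mean over the 4 replicate numbers of 0.45 ± 0.09 (SD, log2, median of the list) and values of 0.45, 0.55, 0.46 and 0.32 in replicates 1, 2, 3 and 4. Fibroblasts or pericytes carried over stay open as a source: their markers together were higher by 0.375 ± 0.256 (SD), in 4 of 4 numbers, although they were highest in replicates 3 and 4 (0.548 and 0.640, against 0.129 and 0.184 in replicates 1 and 2), where the smooth muscle genes were not. A larger share of basal or myoepithelial cells, which also make these proteins, stays open as well: basal genes outside the smooth muscle list were higher by 0.363 ± 0.303 (SD), in 3 of 4 numbers, although they were at -0.021 in replicate 2, where the smooth muscle genes were highest, and at 0.71 in replicate 4, where those were lowest, and 4 numbers are too few to test such a relation. A lower share of luminal cells cannot be told apart from these, because the fibroblast minus endothelial difference it depends on was 0.137 ± 0.141 (SD); luminal genes themselves were at 0.042 ± 0.084 (SD), above 0 in 3 of 4 numbers, which shows no fall but could hide a small one in an abundant cell type, and macrophage markers were at -0.0145 ± 0.794 (SD). A change of expression within the tumour cells after loss of Cldn7 remains untested, since the libraries hold whole organoids.

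Nfe2l2 differed between the hairpins by -1.06 (log2), although both lower Cldn7. An influence of the amount of Cldn7 left that acts in 1 direction is argued against, since Nfe2l2 moved from the control by 0.57 (SE 0.06) with hairpin 1 and by -0.49 (SE 0.06) with hairpin 2 while both lowered Cldn7. Scaling moves all genes of a library alike. The smallest difference of Nfe2l2 over 3 scalings was -1.058 (SE 0.0569), where the median of all genes was 0.00821. This argues against scaling as the source of the difference of Nfe2l2 from the other genes. The other 2 scalings moved that median by only -0.00531 and 0.00091, so a shift common to all genes was not put to the test. If the transcript change carries over to NRF2 activity, its target genes should follow: over 23 targets not examined before, the median of hairpin 2 minus hairpin 1 had a mean of -0.438 ± 0.151 (SD) over the 4 replicate numbers and was below 0 in all 4, so the change may extend to the pathway. Whether it comes from an effect of a hairpin outside Cldn7 or from another difference between the cultures was not tested.

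Between the hairpins, 1 gene differed without the replicate number and 585 with it. With hairpin 2 minus hairpin 1 on the log2 scale, Mfap4 was at 2.07, Crabp1 at 1.90, Meg3 at 1.60, Rian at 1.60 and Gsg1l at 1.52, while Gsta3 was at -1.76, Car8 at -1.69, Ccnjl at -1.38, Ceacam10 at -1.28 and Rdh12 at -1.25. These came forward because the edgeR test of the difference between the hairpins passed the threshold.

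In 40 of 228 sets of 4 libraries, 1 library lay far from the other 3 by Dixon's ratio. Its rate of about 1 in 20 by chance holds for independent sets of normally distributed values. Most of these sets were untransformed CPM of named genes, and libraries with the same number moved together. The 40 can therefore not be set against that rate. In CPM, Pdgfrb stood at 123 in the control library of replicate 4 (7.25 to 19.3 in the other 3), 169 with hairpin 1 (9.68 to 15.6) and 218 with hairpin 2 (11.2 to 24.9). Col4a2 in replicate 4 stood at 345, 602 and 542 CPM in the control, hairpin 1 and hairpin 2 groups, and Mfap4 at 18.1, 14.7 and 60.7 CPM. Meg3 stood at 31.1 and 23.0 CPM and Penk at 6.07 and 4.81 CPM in replicate 4 of the control and hairpin 1. Bgn stood at 1367 and 1631 CPM, Cdh11 at 187 and 220 CPM and Prrx1 at 61.2 and 87.6 CPM in replicate 4 of hairpin 1 and hairpin 2. Colgalt2 stood at 24.6 CPM in control replicate 4, Wfdc18 at 231 CPM in hairpin 1 replicate 4 (507 to 529 in the other 3) and Cldnd1 at 82.2 CPM in hairpin 2 replicate 4.

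In replicate 3, Msx3 stood at 57.4, 36.1 and 7.33 CPM in the control, hairpin 1 and hairpin 2 groups, above the rest of each. Aldoa stood at 5572 and 3643 CPM in the control and hairpin 1, Car8 at 20.6 CPM and Nfe2l2 at 121 CPM in the control, Cldn7 at 44.2 CPM with hairpin 1 (29.0 to 31.1 in the other 3), and Podxl2 at 2.36 CPM with hairpin 2. The hairpin 1 library of replicate 3 had counts in 17828 genes, where the other 3 had 20047 to 20178. In replicate 2, Acta2 stood at 246 CPM in the control (85.0 to 105 in the other 3), Aldh1a3 at 406 and 239 CPM in the control and hairpin 2, Cntn2 at 52.2 and 70.6 CPM and Irx4 at 7.56 and 12.1 CPM in the control and hairpin 1. In replicate 1, Lgr5 stood at 3.63 CPM in the control (10.8 to 12.1 in the other 3).

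Other splits of the samples were fitted with the libraries compared alone. These fits kept the filter and scaling set on all libraries and estimated no dispersion for single genes. Their real counts may therefore differ from those of the other fits, also of fits that held only the groups compared. With the replicate number and both hairpins as 1 group, the real split gave 48 genes and 2 of 45 splits, the real one included, gave as many. The other of these 2, with 677 genes, put all hairpin 2 libraries on 1 side. Each set of 45 splits held the real split and a random draw from a larger number of possible splits, so its share depends on the draw. The share lay under 0.05, but 1 more such split would have raised it over that. The 8 tests of splits were also not adjusted for their number, so this test cannot exclude chance. Without the replicate number chance cannot be excluded: as many genes came from 7 of 45 splits for both hairpins (real 1, highest other 5322) and 3 of 35 between the hairpins (real 1, 2975). For hairpin 1 (real 0, highest other 2881) and hairpin 2 (real 0, 2837) 35 of 35 splits gave as many. A real count of 0 fixes that in advance, so the tests of these 2 contrasts decide nothing. The 2881, 2837 and 2975 came from the splits of replicates 1 and 2 against 3 and 4, which is a structure of the samples. With the replicate number, the 8 splits of each pair of groups are too few for a share under 0.05; the real counts were 371 for hairpin 1, 107 for hairpin 2 and 489 between the hairpins, the highest other was 0, and 1 of 8 splits, the real one, gave as many.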

How the results depend on the processing

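The alternatives with the replicate number in the model, those of the lists included, the fits of replicates 1 and 2 or 3 and 4 alone, and the fit of all hairpin libraries as 1 group were chosen after the data were seen; the others were planned. No scaling moved the median of all genes by more than 0.1 (log2). The fold change of Cldn7 was negative in every fit against the control, and the smooth muscle list over both hairpins had a mean of 0.43 to 0.59 (log2, relative to all genes) and passed camera's test when any single library was left out. With the replicate block it was 0.51 with a range of 0.43 to 0.60, lost its call with an estimated correlation (0.51; adjusted p = 0.517), and was 0.54 in replicates 1 and 2 alone and 0.47 in replicates 3 and 4 alone. At the same depths, simulated data gave back 15% of 1.5-fold changes without the replicate block and 70% with it.

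Without the replicate block, 1 gene passed in each contrast and 1 was shared by both hairpins. With the replicate block as the alternative the counts moved to 304 for both hairpins, 124 for hairpin 1, 981 for hairpin 2, 585 between the hairpins and 52 shared, because the block takes the replicate differences out of the residual spread. DESeq2 gave 43, 27, 61, 49 and 8 without the block. With only the libraries of the 2 groups in the fit, edgeR gave 0 for hairpin 1 (224 genes at an unadjusted p under 0.05), 0 for hairpin 2 (490) and 0 shared, where fewer samples estimate the spread; Cldn7 was then at -2.06 (edgeR adjusted p = 0.259) and -2.32 (0.0578). The test against a 1.5-fold change gave 0 between the hairpins (61 genes at an unadjusted p under 0.05). Over the other settings without the block the counts moved by less than 1.5 times.

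With the replicate block in the model, DESeq2 called 1161 genes for both hairpins, 607 for hairpin 1, 1860 for hairpin 2, 1436 between the hairpins and 240 shared, and of the 304 edgeR called for both hairpins it shared 303; the cause was not tested. The test against a 1.5-fold change, which asks for larger effects, called 1, 1, 3, 6 and 1. With fewer samples, replicates 1 and 2 alone gave 25, 9, 82, 84 and 5, and replicates 3 and 4 alone 5, 1, 327, 42 and 1. Fits of only the 2 groups gave 390 for hairpin 1, 97 for hairpin 2 and 32 shared, and all hairpin libraries taken as 1 group gave 48 against the control; the cause was not tested. Other scalings, filters, the robust trend and limma-voom stayed within 1.5 times, from 279 to 393 for both hairpins.

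Leaving out 1 library at a time, Cldn7 ranged from -2.33 to -2.04 over both hairpins, -2.24 to -1.91 for hairpin 1, -2.45 to -2.16 for hairpin 2 and -0.35 to -0.08 between the hairpins. Its hairpin 1 call was lost without control replicate 1 or 2 or hairpin 1 replicate 1, 2 or 4. These 5 omissions took the count without the block from 1 to 0 for hairpin 1 (250, 334, 234, 253 and 369 genes at an unadjusted p under 0.05) and for the shared genes. The counts without the block ranged from 1 to 1 for both hairpins, hairpin 2 and between the hairpins, and from 0 to 1 for hairpin 1 and shared.

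With the block and 1 library left out, the counts ranged from 39 to 554 for both hairpins, 2 to 344 for hairpin 1, 342 to 1076 for hairpin 2, 165 to 672 between the hairpins and 2 to 119 shared, and the cause was not tested. The count for both hairpins was 54, 93 and 39 without control replicates 1, 3 and 4, 100, 110, 135 and 105 without hairpin 1 replicates 1 to 4, and 554 and 135 without hairpin 2 replicates 3 and 4. For hairpin 1 it was 10, 71 and 31 without control replicates 1, 3 and 4, 2, 8, 11 and 26 without hairpin 1 replicates 1 to 4, and 344 without hairpin 2 replicate 3. For hairpin 2 it was 369, 342 and 571 without control replicates 1, 3 and 4, 619 without hairpin 1 replicate 2, and 437 and 385 without hairpin 2 replicates 1 and 4. Between the hairpins it was 197, 205, 165 and 189 without hairpin 1 replicates 1 to 4, and 252 and 296 without hairpin 2 replicates 1 and 4. Shared genes numbered 8, 29 and 17 without control replicates 1, 3 and 4, 2, 7, 7 and 18 without hairpin 1 replicates 1 to 4, and 26, 119 and 29 without hairpin 2 replicates 1, 3 and 4.

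Some values turned round. With the replicate block and replicates 1 and 2 alone, Acta2 between the hairpins was -0.0107, the cholesterol list 0.0037 between the hairpins and 0.044 for hairpin 2, and the protease list -0.15 for both hairpins and -0.13 for hairpin 2. Without the block and with 1 library left out, which leaves the replicate sets unequal between groups, the cell cycle list ranged from -0.27 (camera adjusted p = 0.0181) to 0.66 for both hairpins and from -0.094 to 0.84 for hairpin 1, both lowest without control replicate 4. The collagen list ranged from -0.19 to 0.89 for hairpin 2 and the mesenchymal list from -0.14 to 0.93 between the hairpins, both lowest without hairpin 2 replicate 4. The hypoxia list for hairpin 2 ranged from -0.50 to 0.076, highest without control replicate 3, and the cholesterol list between the hairpins from -0.42 to 0.14, highest without hairpin 1 replicate 3. With the block all but the last kept their direction, from 0.040 to 0.43 and 0.22 to 0.61 for the cell cycle, 0.26 to 0.52 for collagens, 0.20 to 0.48 for mesenchymal and -0.33 to -0.17 for hypoxia genes. For the cholesterol list camera's direction turned without hairpin 2 replicate 3, although the mean stayed below 0, at -0.34 to -0.00899 for hairpin 2 and -0.32 to -0.0044 between the hairpins. The cause was not tested. Among the named genes, 951 of their values under the other settings kept direction and side of the threshold, 466 were no longer past it, 9 newly passed and 1 turned round; with 1 library left out, 1000 kept both, 421 were no longer past it and 7 newly passed. For the lists these numbers were 103, 64, 0 and 1, and with 1 library left out 265 kept both, 65 were no longer past the threshold and 6 turned round. For the lists called with the block these numbers were 139, 121, 0 and 4, and with 1 library left out 470, 56, 0 and 2. The block moved the number of list calls from 6 to 12 for both hairpins, 4 to 7 for hairpin 1, 9 to 14 for hairpin 2 and 9 to 11 between the hairpins, where it ended that of immediate early genes. Apart from gene counts, list calls and genes other than Cldn7, it changed no call.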

Other observations

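The list of NRF2 targets was made after Nfe2l2 had been seen to differ, and those tests were chosen then. Genes that NRF2 is known to switch on followed Nfe2l2 between the hairpins. Of the 23 targets not examined before the list was made, 12 were lower with hairpin 2 than with hairpin 1 and 0 higher by edgeR's adjusted p, with the replicate number in the model. Among them were Hmox1, the haem oxygenase (-0.80, SE 0.12), Txnrd1, a thioredoxin reductase (-0.52, SE 0.06), the ferritin heavy chain Fth1 (-0.71, SE 0.10), Slc7a11, the cystine importer (-0.71, SE 0.16), Nqo1, a quinone reductase (-0.56, SE 0.10), and Pgd, an enzyme of the pentose phosphate pathway (-0.56, SE 0.06). Ugdh was the exception in sign (0.02, SE 0.07). The 8 targets already seen among the changed genes, such as Gstm1 (-1.18, SE 0.08), Gstp1 (-1.12, SE 0.10) and Aox1 (-1.06, SE 0.08), had a mean of 4 pair medians of -0.959 ± 0.133 (SD).

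Against the control, the 23 targets had a median of 0.21 with hairpin 1, where 0 passed singly (camera p = 8.32e-06, and p = 0.0859 with an estimated correlation). Their medians over the 4 replicate numbers averaged 0.160 ± 0.216 (SD) with hairpin 1, within the SD of 0, and were below 0 in 1 number. With hairpin 2 the median was -0.27 and 6 were lower (camera p = 2.2e-08; p = 0.0419 with an estimated correlation). Between the hairpins camera gave p = 3.5e-17 (p = 0.00812 with an estimated correlation). These list tests were not adjusted for the other lists.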
